A study of Mus musculus with 4 samples.

How the data were processed

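Cultured mouse 4T1 cells with a scrambled or an Ldha hairpin were measured on 4 arrays, 2 per group. The labels' protocols state Trizol extraction of total RNA, an input of 400 ng and biotin labelling with a whole-transcript kit of Affymetrix. The authors deposited log2 expression values, made with RMA and R 3.4.0 per the submitters' processing notes. RMA as commonly run corrects the background, applies quantile normalization and summarises the probes of a set. The scale was checked from the values, which ran from 1.23 to 12.91 over all 41345 probe sets. The annotation version used with RMA is not given in the sources used here, and scanner files were not used here. Groups and replicate numbers were taken from the sample titles, since the cell type label names LDHA in both groups, and 0 columns of values were left out.

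The value table held 41345 probe sets, called probes here. A platform annotation table gave exactly 1 gene symbol for 23521, several for 1814 and none for 16010. Only the first kind entered, and of these, 23328 had a gene identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. For the 1082 genes with more than 1 probe, the probe with the highest mean over the 4 arrays was kept, which left 22180 genes. No filter on dim genes was applied. The build behind the platform annotation is not given in the sources used here, so no positions are printed, and the RefSeq table was used only for names and for which genes neighbour each other. Array signals near the floor are compressed, so the fold of a dim gene may understate its change. The fold of a gene whose probes also bind another transcript may be off as well, in a direction not known here. The median of the brighter group's mean was 4.10.

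The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values as deposited, over all 4 arrays, with no covariate. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and every test was two-sided. The fit had 2 residual degrees of freedom and 4.52 prior ones, and the median SE of a log2 change was 0.09. Unless another test is named, an adjusted p of a gene is from this limma fit. SDs are over the 2 arrays of a group. Depth in reads does not apply to arrays, whose number limits the precision.

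The rule for genes named in the text was set before the data were examined. It took Ldha with Ldhb, Ldhc and Ldhd, 16 genes whatever their values, and the 12 largest rises and 12 largest falls. A rise or fall counted where it was past the threshold, had both arrays of 1 group beyond both of the other, and had a brighter group at or above the median of that quantity. Predicted genes were passed over. From each gene list the up to 4 members with the smallest p could be named; other members named in the text were chosen after their values were seen. Also set before the data were examined were 31 gene lists with 630 entries, of which 564 matched a tested gene. The lists covered metabolism, stress responses, cytokines and inflammation, the cell cycle, ribosomes, lipids, epithelial and mesenchymal state, matrix, and markers of fibroblasts, leukocytes and endothelium. The 30 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the lists. Camera with a correlation estimated per list and the self-contained fry test were alternatives. The first of these uses the 2 residual degrees of freedom of the fit, which makes it hard for a list to pass.

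The code was tested on simulated data with 22180 genes, 200 of them changed, in 10 runs. It recovered 11.2% of genes changed by 0.5 on the log2 scale, 91.5% of those changed by 1 and 99.7% of those changed by 2, and 4.53% of its calls were false. A shifted list was recovered in 10 of 10 runs and an unshifted list was called in 0, at an unadjusted camera p under 0.05. The simulated noise was independent between genes, so these runs cannot show how often lists of correlated genes are called falsely. Each gene's variance was drawn from the prior that limma had fitted, regardless of its level. The share of false calls therefore checks the code and not whether that model holds on these arrays. The 200 changed genes were fewer than the 1410 called in the data, so the recovered percentages need not hold there.

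Alternatives set before the data were examined were the replicate number as a block, a filter that kept genes at or above the median level or above the 25th percentile, quantile normalization applied again, centring each array on its median, the mean of a gene's probes, every probe tested, eBayes with a trend or robust, leaving out each array, and a relaxed threshold of 0.1. The first 13 of these settings, counting each array left out as 1, are the alternative settings to which counts in the text refer. Some dim genes were outside a filter and had fewer. Figures were drawn with matplotlib 3.10.9.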

Results

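RNA was measured in cultured 4T1 cells, a mouse mammary carcinoma line that grows in culture and as tumours in BALB/c mice. The cells carried either a short hairpin RNA with a scrambled sequence (scramble) or one against Ldha (shLDHA), the gene of the lactate dehydrogenase A subunit, which converts pyruvate to lactate at the end of glycolysis. The cells that took up the Ldha hairpin had been selected with puromycin at 10 µg/ml and pooled. The labels do not say whether the scramble cells were selected too, so a difference in selection cannot be told apart from the knockdown. Both kinds of cell were grown for 24 hours in complete medium, and 400 ng of total RNA per sample was labelled for whole-transcript Affymetrix arrays. Each group held 2 arrays, so 4 arrays were compared. Nothing in the labels says that the 2 replicates of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and their small number limits the precision of every value below.

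The 4 arrays had nearly equal medians over all 41345 probes, at 3.87 and 3.87 in scramble and 3.90 and 3.87 in shLDHA on the log2 scale. Across genes, which are not independent replicates, the 2 scramble arrays correlated at r = 0.997 and the 2 shLDHA arrays at r = 0.997. Arrays of different groups correlated at r = 0.993. The SD of the differences was 0.17 between the scramble arrays and 0.18 between the shLDHA arrays. It was 0.28 to 0.29 between arrays of different groups.

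The targeted transcript was lower in the knockdown. Ldha (probe 17478225) read 6.69 and 6.96 on the scramble arrays and 6.31 and 6.15 on the shLDHA arrays. The means were 6.82 ± 0.20 (SD, n = 2) and 6.23 ± 0.11 (SD, n = 2), a log2 change of -0.59 (SE 0.12), or 1.51-fold lower. The limma test gave an adjusted p of 0.0390. The other genes of the family did not pass. Ldhb, which encodes the B subunit, had a log2 change of 0.02 (SE 0.09), the testis form Ldhc one of -0.03 (SE 0.11) and the D-lactate dehydrogenase gene Ldhd one of -0.15 (SE 0.10). Ldha passed in 8 of 13 alternative settings. Among the losses were the fits without scramble replicate 2 (adjusted p = 0.128), without shLDHA replicate 1 (0.0965) and without shLDHA replicate 2 (0.163), and the fit of every probe (0.168). Over the 13 settings the adjusted p ran from 0.00548 to 0.168 and the log2 change from -0.73 to -0.45.

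The comparison asks which other transcripts differed between the Ldha knockdown and the control cells. Of the 22180 genes, 1410 (6.36%) passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 747 of them higher and 663 lower in shLDHA. The large changes leaned to falls, since 99 genes fell and 62 rose at least 2-fold. At an unadjusted p under 0.05, 4778 genes passed. Leaving out an array cuts the residual degrees of freedom from 2 to 1, so fewer calls are expected whichever array goes. The counts rest on all 4 arrays. Without scramble replicate 1 they were 322 higher and 314 lower, without scramble replicate 2 they were 310 and 316, without shLDHA replicate 1 they were 195 and 221, and without shLDHA replicate 2 they were 150 and 220. Of the 89 genes past the threshold that the rule for named genes gave, 31 lost the call without at least 1 array, 18 and 19 without scramble replicate 1 and 2, and 27 and 30 without shLDHA replicate 1 and 2. In the alternative settings that kept all 4 arrays and 1 value per gene, the count of genes changed at least 2-fold stayed between 152 and 161. With every probe tested, 119 probes changed this far, 99 of them shared with the 161 genes of the main fit.

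Of the 12 largest falls by the rule for named genes, 5 were in the list of cytokines and chemokines fixed before the data were examined. Il1a, which encodes the cytokine interleukin 1 alpha, went from 10.69 ± 0.07 (SD, n = 2) to 5.61 ± 0.04 (SD, n = 2), 33.9-fold lower (log2 change -5.08, SE 0.09, adjusted p = 8.32e-06). Lcn2, which encodes the siderophore-binding protein lipocalin 2, fell 13.7-fold (adjusted p = 2.06e-05). Csf3, the gene of the granulocyte growth factor G-CSF, went from 9.02 ± 0.17 (SD, n = 2) to 5.94 ± 0.04 (SD, n = 2), 8.43-fold lower (adjusted p = 0.000164). Of the neutrophil chemoattractants, Cxcl5 fell 8.10-fold and Cxcl1 7.07-fold, and the chemokines Ccl5 and Cxcl10 fell 8.88-fold and 5.10-fold. The rest were Prnd, a prion protein relative (log2 change -3.67), the collagenase gene Mmp13 (-3.22), the membrane-anchored semaphorin gene Sema7a (-2.64), the ubiquitin ligase gene Neurl3 (-2.46) and the interferon-inducible Oasl1 (-2.45). Of these 12, 11 passed in every alternative setting in which they were tested. The exception was Oasl1, whose adjusted p was 0.0526 when every probe was tested. Prnd has a dimmer second probe, which changed by -0.20, and the mean of both gave -1.94.

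**Figure D1:**
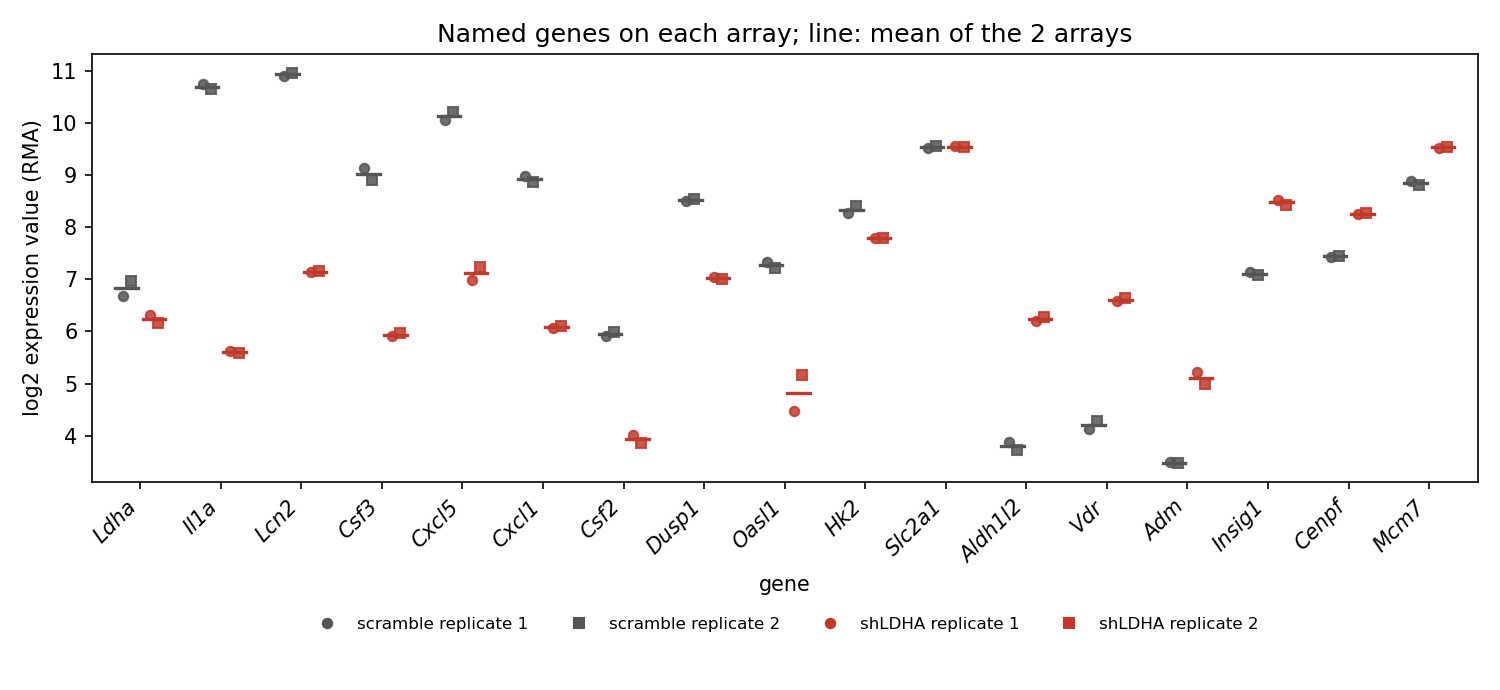
The plot shows the log2 expression value of 17 named genes on each of the 4 arrays, with scramble in grey and shLDHA in red, replicate 1 as circles, replicate 2 as squares, and a line at the mean of the 2 arrays of a group. Il1a shows the deepest fall, from 10.69 to 5.61, while Ldha moved from 6.82 to 6.23 and Slc2a1 read 9.54 in both groups.

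Cytokines and chemokines that act on myeloid cells fell as a group. Of the 27 genes of this list, 13 were lower and 0 higher in shLDHA over all genes tested, and 17 were lower and 1 higher adjusted over the list alone. The median log2 change was -0.39, and -1.20 over the members at or above the median level of all genes. Besides the genes above, Csf2, the gene of the growth factor GM-CSF, fell 4.05-fold (log2 change -2.02, SE 0.09), Cxcl3 changed by -2.16, Ccl20 by -1.47, Cxcl16 by -1.21 and the interleukin 6 family cytokine gene Lif by -1.19. Cxcl2, Ccl2 and Il6 did not pass, with log2 changes of -0.06, -0.36 and -0.26; their scramble means lay between 2.57 and 3.85. Among 14 leukocyte markers Cd68 fell (-0.91) and 13 did not pass. Camera with a preset correlation gave an adjusted p of 2.40e-15, and with an estimated correlation the adjusted p was 0.169. A second, dim Csf2 probe changed by -0.32, and the mean of both probes gave -1.17.

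Genes induced by NF-kB, a transcription factor of inflammation, fell alongside. Of 17 tested, 11 were lower and 0 higher, and 12 were lower adjusted over the list alone, with a median log2 change of -0.54. Lcn2 and Cxcl10 led the list. They were followed by Nfkbiz (-1.29, SE 0.08), which encodes a nuclear member of the IkB family, and Relb (-0.93, SE 0.10), which encodes an NF-kB subunit. The inhibitor genes Tnfaip3 (-0.55) and Nfkbia (-0.53) also fell. The camera adjusted p was 1.54e-12 with a preset correlation, and the adjusted p was 0.169 with an estimated correlation. The list shares 1 gene, Csf1 (-0.67), with the cytokine list. Tnfaip3, Nfkbia and Csf1 passed in 8, 7 and 10 of the 13 alternative settings.

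Immediate early genes, which growth factors and stress switch on within minutes, were lower on balance. Of 20 tested, 10 fell and 1 rose over all genes tested, and 11 fell and 2 rose adjusted over the list alone (median log2 change -0.42). The phosphatase genes Dusp1 (-1.49, SE 0.08) and Dusp5 (-1.28, SE 0.10), the matrix protein gene Ccn1 (-1.43, SE 0.09) and Ier3 (-1.29, SE 0.10) had the smallest p-values. Jun changed by -0.92 and Egr1 by -0.88, while Fos rose by 0.75 and passed in 9 of the 13 alternative settings. The camera adjusted p was 1.08e-07, and it was an adjusted p of 0.463 with an estimated correlation.

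Interferon-stimulated genes, part of the antiviral response, were also lower. Of 26 tested, 8 fell and 0 rose, and 11 fell adjusted over the list alone, with a median log2 change of -0.26, and of -0.45 over the members at or above the median level of all genes. Oasl1 fell 5.47-fold, Ifit1 3.26-fold, Oasl2 2.98-fold and the RNA sensor gene Ifih1 2.07-fold. Oasl1 had an SD of 0.48 over the shLDHA arrays, against 0.08 over the scramble arrays. The list passed camera with an adjusted p of 2.57e-08, and the adjusted p was 0.351 with an estimated correlation.

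A smaller shift downward was seen for MYC targets and genes of ribosome assembly. Of 20 tested, 3 fell and 0 rose, and 5 fell adjusted over the list alone (median log2 change -0.16). The 3 were Odc1, which encodes the first enzyme of polyamine synthesis (-0.77, SE 0.09), the RNA polymerase I subunit gene Polr1b (-0.57, SE 0.08) and the nucleolar Gnl3 (-0.41, SE 0.09). Myc itself, at 11.26 in scramble and 11.02 in shLDHA, did not pass (log2 change -0.24, adjusted p = 0.172). The adjusted p of camera was 9.70e-04, and the adjusted p was 0.288 with an estimated correlation. The list median was -0.09 without shLDHA replicate 2. Polr1b passed in 9 of the 13 alternative settings, Gnl3 in 6 and Myc in 1.

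Among the 12 largest rises by the rule for named genes, Aldh1l2, which encodes a mitochondrial folate enzyme, rose 5.37-fold, from 3.81 ± 0.11 (SD, n = 2) to 6.24 ± 0.06 (SD, n = 2), with an adjusted p of 0.000164. The vitamin D receptor gene Vdr rose 5.25-fold (log2 change 2.39, SE 0.09). The zinc finger gene Zfp979 (2.20), the band 4.1 family gene Epb41l4a (2.08), the adaptor gene Afap1l2 (1.99), the tight junction gene Cldn9 (1.98), the long noncoding RNA gene Fendrr (1.95) and the caveolin gene Cav1 (1.87) came next. Lurap1l (1.81), the Golgi mannosidase gene Man1c1 (1.78), the cell surface receptor gene Ly9 (1.65) and the matrix protein gene Postn (1.64) made up the 12. Of these 12, 9 passed in every alternative setting in which they were tested. Zfp979, Cav1 and Ly9 lost the call when every probe was tested, with adjusted p of 0.0749, 0.0550 and 0.0736. The scramble means of 5 of the 12 rises, Aldh1l2 among them, lay below the level of 95% of olfactory receptor genes (4.17), so their folds may understate the change, as may those of 2 of the 12 falls that ended below that level. The other Zfp979 probes changed by 0.54 and -0.22, and the mean of all of its probes gave 0.84.

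Genes of cell division rose together. Of 28 genes of G2/M and mitosis, 19 were higher and 0 lower in shLDHA, and 26 were higher adjusted over the list alone, with a median log2 change of 0.47. The centromere protein gene Cenpf rose by 0.82 (SE 0.08), the condensin subunit gene Ncapd2 by 0.87 (SE 0.09), the mitotic kinesin gene Kif20a by 0.76 (SE 0.09) and Hmmr by 0.75 (SE 0.09). Mki67, a common marker of proliferating cells, rose by 0.61. The camera adjusted p was 1.86e-18, and with an estimated correlation the adjusted p was 0.169. Each of the first 4 genes passed in 12 of the 13 alternative settings, and Mki67 in 9.

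Of 25 genes of G1/S and DNA replication, 9 were higher and 0 lower, and 18 were higher adjusted over the list alone (median log2 change 0.30). The replication licensing gene Cdc6 rose by 0.77 (SE 0.09), and the helicase genes Mcm7, Mcm6 and Mcm3 rose by 0.68, 0.67 and 0.60. The adjusted p of camera was 6.69e-11, and the adjusted p was 0.169 with an estimated correlation. Mcm3 passed in 9 of the 13 alternative settings.

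Genes that respond to hypoxia were higher on balance. Of 17 tested, 7 rose and 1 fell over all genes tested, and 8 rose and 1 fell adjusted over the list alone, with a median log2 change of 0.28. Adm, the gene of the peptide hormone adrenomedullin, rose 3.08-fold, from 3.49 ± 0.00 (SD, n = 2) to 5.11 ± 0.16 (SD, n = 2). Ddit4, an inhibitor of mTORC1 signalling, rose 1.99-fold, the carbonic anhydrase gene Car9 rose 1.97-fold and the collagen prolyl hydroxylase gene P4ha1 1.46-fold. Higd1a fell (log2 change -0.46). Vegfa (0.06, adjusted p = 0.767) and Hif1a (-0.24, adjusted p = 0.202) did not pass, and Hif1a is not in this list. The camera adjusted p was 9.18e-04, and the adjusted p was 0.288 with an estimated correlation. The list median was 0.13 without scramble replicate 2. P4ha1 passed in 8 and Higd1a in 7 of the 13 alternative settings. A dimmer Hif1a probe changed by 0.45, and the mean of both was 0.10.

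Genes of cholesterol synthesis and uptake were higher on balance. Of 18 tested, 5 rose and 1 fell, and 9 rose and 2 fell adjusted over the list alone (median log2 change 0.27). Insig1, a sterol-regulated protein of the endoplasmic reticulum, rose 2.58-fold (log2 change 1.37, SE 0.09). The synthesis enzyme genes Cyp51, Fdft1, Sqle and Nsdhl rose by 0.63, 0.58, 0.53 and 0.44, while Sc5d fell by 0.64 on the log2 scale. The camera adjusted p was 0.0163, and the adjusted p was 0.351 with an estimated correlation. Cyp51 passed in 10, Fdft1 and Sc5d in 9, Sqle in 8 and Nsdhl in 7 of the 13 alternative settings.

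Lists of serine and one-carbon metabolism and of fatty acid oxidation also passed, each with a single member past the threshold over all genes tested. In the first, Aldh1l2 rose and the remaining 11 of 12 genes did not pass, with Tyms at 0.38 and Psat1 at 0.25. Adjusted over the list alone, 2 were higher and 0 lower, and the median log2 change was 0.14. Camera gave an adjusted p of 0.0163, which was 0.0554 without scramble replicate 1, and the adjusted p was 0.463 with an estimated correlation. In the second, Hadha, a subunit of the mitochondrial trifunctional protein, rose by 0.62 (SE 0.08) and the remaining 17 of 18 did not pass. Adjusted over the list alone, 3 were higher and 0 lower, and the median was 0.09, or 0.18 over the members at or above the median level of all genes. Camera gave an adjusted p of 0.0389, the adjusted p was 0.616 with an estimated correlation, and the list passed in 7 of the 13 alternative settings, not without scramble replicate 1 (0.0853), scramble replicate 2 (0.0830) or shLDHA replicate 2 (0.202). Hadha passed in 9 of the 13.

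**Figure D2:**
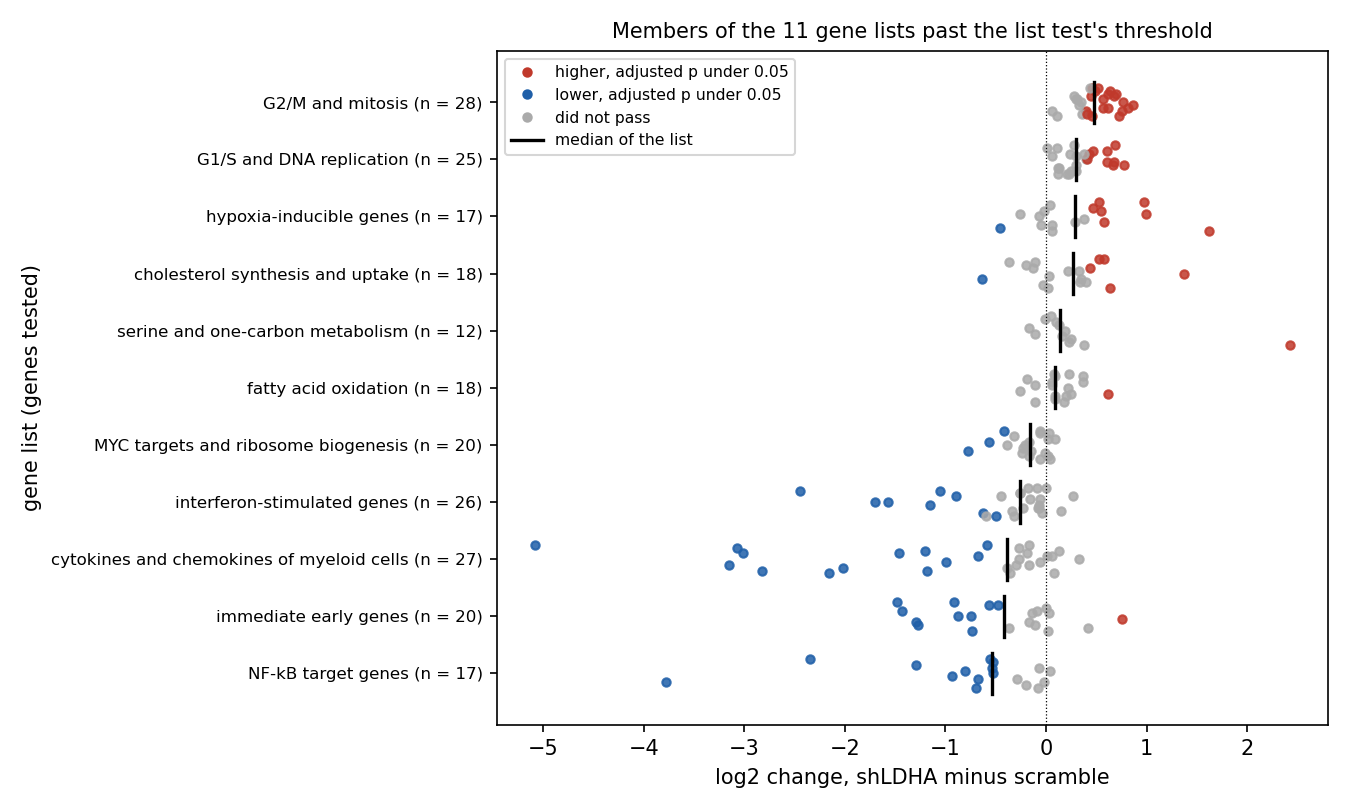
Each point is the log2 change, shLDHA minus scramble, of 1 gene of the 11 lists past the threshold of the camera test with a preset correlation, in red or blue where the gene itself passed as higher or lower and in grey where it did not. The black lines are list medians, which run from -0.54 for NF-kB target genes to 0.47 for G2/M and mitosis, and the vertical position of a point within a list carries no meaning.

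Glycolysis genes other than Ldha did not move as a group. Of 19 tested, 2 rose and 2 fell, both over all genes tested and adjusted over the list alone. Pfkfb3, which encodes an enzyme that makes the activator of phosphofructokinase, changed by -0.78 (SE 0.08), and the hexokinase gene Hk2 by -0.54 (SE 0.09). The phosphofructokinase gene Pfkl rose by 0.48 (SE 0.09) and Pgam1 by 0.40 (SE 0.08). The glucose transporter gene Slc2a1 (-0.01), the pyruvate kinase gene Pkm (-0.07) and the lactate transporter genes Slc16a1 (-0.13) and Slc16a3 (0.03) did not pass. The list median was 0.03 and the camera adjusted p was 0.889. Hk2, Pfkl and Pgam1 passed in 9, 7 and 6 of the 13 alternative settings.

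The other metabolic lists held few calls. Of 39 nuclear genes of oxidative phosphorylation, Ndufs1 rose by 0.40 (SE 0.08) and no other passed (camera adjusted p = 0.206), and 0 passed adjusted over the list alone. Ndufs1 passed in 7 of the 13 alternative settings. No gene passed among 19 of the tricarboxylic acid cycle (0.378) or 13 of fatty acid synthesis (0.933), where 0 passed adjusted over the list alone as well. Of 6 pentose phosphate genes 0 passed over all genes tested, and 1, Pgd (0.40), was higher adjusted over the list alone (camera adjusted p = 0.811). The list of mitochondrially encoded genes had 0 tested members.

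Of the C/EBP transcription factors, Cebpd fell by 1.04 on the log2 scale (SE 0.08) and 4 of 5 did not pass, with the same count adjusted over the list alone. Cebpb read 8.15 ± 0.04 (SD, n = 2) in scramble and 8.06 ± 0.32 (SD, n = 2) in shLDHA, a log2 change of -0.09 (SE 0.15, adjusted p = 0.802). The camera adjusted p of the list was 0.0859. Matrix proteins and proteases had the same adjusted p of 0.0859. Over the genes at or above the median level, camera gave the matrix list 0.0468, with a list median of -0.22 against -0.04 in the main fit. The fry adjusted p was 0.0164 for the matrix list and 0.0295 for the C/EBP list. Of 23 tested, 6 fell and 1 rose, and 7 fell and 3 rose adjusted over the list alone. Mmp13, Mmp3 (-1.83), Tnc (-1.16), Plaur (-0.57), Mmp10 (-0.52) and Col4a2 (-0.39) fell, and Thbs1 rose by 1.24. Plaur, Mmp10 and Col4a2 passed in 9, 8 and 7 of the 13 alternative settings.

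In the remaining lists, members went both ways or did not pass. Of 21 epithelial genes, 6 rose and 2 fell, and 8 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.872). The claudin genes Cldn7 and Cldn3 changed by -1.06 and -0.97, and Rab25 and Ocln by 0.71 and 0.62. Of 17 mesenchymal genes only Tgfbi passed (1.12; camera adjusted p = 0.811), and adjusted over the list alone 1 was higher and 1 lower. Of 20 genes of the ATF4 stress response, 4 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone (0.378), with Vldlr at 1.54, Fgf21 at 0.99 and Chac1 at -0.42. Of 16 genes of the unfolded protein response, Sel1l rose by 0.42 and Hyou1 changed by -0.42, with the same counts adjusted over the list alone (0.846). Of 14 NRF2 target genes, Gsta4 rose by 1.21 while Osgin1 and Abcc1 changed by -0.56 and -0.55, and 4 rose and 3 fell adjusted over the list alone (0.933). Of these genes, Ocln passed in 10 of the 13 alternative settings, Osgin1 and Abcc1 in 8, and Chac1, Sel1l and Hyou1 in 7.

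Of 32 genes of autophagy and lysosomes, 4 rose and 1 fell, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.933). The lysosomal hexosaminidase gene Hexa rose by 1.47, and Gabarapl2 changed by -0.63. Of 15 genes of MHC class I antigen presentation, Tap2 and Psme1 rose by 0.70 and 0.48 and the transactivator gene Nlrc5 changed by -1.49 (0.846), with 4 higher and 3 lower adjusted over the list alone. Cd274, the gene of the immune checkpoint ligand PD-L1 and a member of that list, did not pass (-0.26, adjusted p = 0.167). Of 17 p53 target genes, Trp53inp1 and Perp rose by 0.66 and 0.65 and Plk2 changed by -1.36 (0.811), with 4 higher and 5 lower adjusted over the list alone. Tap2 and Perp passed in 10 of the 13 alternative settings, Gabarapl2 in 8 and Psme1 in 7. No gene of 26 for cytosolic ribosomal proteins passed, over all genes tested or adjusted over the list alone (0.933). The median, the mean and the tests differed in sign for the glycolysis, MHC class I, fatty acid synthesis, ribosomal protein, mesenchymal and fibroblast lists, none of which passed.

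Markers of other cell types were mostly dim, with median scramble levels of 3.05 for macrophage and leukocyte, 3.53 for fibroblast and 3.01 for endothelial markers. Of 14 macrophage and leukocyte markers, Cd68 fell by 0.91 on the log2 scale (SE 0.10), from 7.46 to 6.55, and the remaining 13 did not pass, with the same count adjusted over the list alone (median -0.03, camera adjusted p = 0.829). Of 10 fibroblast markers, Postn rose and 9 did not pass, with the same count adjusted over the list alone (0.933). Of 9 endothelial markers, 0 passed, over all genes tested or adjusted over the list alone (0.378).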

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

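The alternatives were planned before the data were examined. With an array left out, its group has 1 array, which is assumed to vary like the other group. Such a fit has 1 residual degree of freedom. The count of genes changed at least 2-fold stayed between 119 and 168. Among named genes other than Ldha, 1695 values kept direction and side of the threshold, 152 lost the call, 53 gained it and 14 changed sign. Of the 11 gene lists, 9 passed in each of the 13 alternative settings, serine and one-carbon metabolism in 12 and fatty acid oxidation in 7.

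With the replicate number as a block, 433 genes were higher and 405 lower, of which 417 and 399 were among the calls without it, and Ldha (-0.59) had an adjusted p of 0.0734. Same-numbered arrays did not deviate together (r = -0.03 across genes). With 2 arrays per group this cannot tell whether the arrays were paired in culture or processing, which the labels do not state. The block changed the call of 11 other named genes and of 1 list, fatty acid oxidation (adjusted p = 0.0563). With genes at or above the median level, 1442 were higher and 1341 lower, with fewer genes to adjust over and a lower prior SD (0.0835 against 0.0968). With an eBayes trend the counts were 1425 and 1381, where the prior degrees of freedom rose from 4.52 to 7.97. With every probe tested, 42 probes were higher and 86 lower, of which 33 and 71 were shared with the main calls. The prior degrees of freedom then fell to 2.67 and 41345 probes were adjusted over, and Ldha (-0.59) had an adjusted p of 0.168. At an adjusted p under 0.1 in the main fit, 1271 genes were higher and 1120 lower. With a correlation estimated per list, 0 lists were higher and 0 lower. At an unadjusted p under 0.05, camera then passed 2 and 2. The estimates lay below the preset 0.01 for the cytokine (-0.03), NF-kB (-0.02), hypoxia (-0.02), MYC (-0.04), cholesterol (-0.04) and G1/S (-0.001) lists. A higher correlation therefore does not account for the loss of their calls. With an estimated correlation, camera uses the 2 residual degrees of freedom of the fit, which it does not do with a preset one. For the cytokine list the unadjusted camera p went from 1.6e-16 with the preset to 0.0114. The adjusted p with an estimated correlation thus says little about how far these calls depend on correlation between genes. Among the called lists the estimate was highest for immediate early genes (0.39), then interferon-stimulated genes (0.14). With fry, 5 lists were higher and 7 lower.

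Leaving out each array gave 150 to 322 genes higher and 220 to 316 lower (322, 310, 195 and 150, and 314, 316, 221 and 220, without scramble 1, scramble 2, shLDHA 1 and shLDHA 2), and Ldha between -0.73 and -0.45.

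Some lists that did not pass also changed direction between settings, such as ribosomal proteins, down in the main fit and up over genes at or above the median level. Among named genes, changes of sign were all in genes that did not pass, and the cause was not tested. Slc2a1 was 0.0110 with quantile normalization again, 0.00128 with the mean of probes, and -0.0277 to 0.0103 with an array left out. Hif1a was 0.104 with the mean of probes. With an array left out, Ldhb ran from -0.0348 to 0.0756, Ldhc from -0.164 to 0.105, Slc16a3 from -0.0758 to 0.136, Cebpb from -0.312 to 0.135, Tie1 from -0.0458 to 0.451 and Cebpg from -0.0667 to 0.00350. Signal over background limits dim genes, since 82 of the 1410 called genes lay below the median level of the brighter group.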

Other observations

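The 6 gene groups of the first paragraphs were put together after the data were examined, as were the tests of leukocyte and fibroblast markers and the medians per chromosome; they describe these arrays and are no independent evidence. Genes of desmosomes and of the cornified envelope, the structures that hold and seal stratified epithelia, were higher on balance in shLDHA. Of 22 tested, 12 rose and 1 fell, with a median log2 change of 0.64. The periplakin gene Ppl rose by 1.08, the desmosomal cadherin gene Dsg2 by 1.01, the transcription factor gene Grhl3 by 1.18 and the keratin gene Krt14 by 0.80, while Dsc2 fell by 0.81 on the log2 scale. Among other desmosome genes, Jup and Perp rose by 0.71 and 0.65, while Dsp (0.19), Pkp1 (0.28), Pkp2 (-0.32) and Pkp3 (0.22) did not pass. The scramble means of Grhl3 (3.76) and Krt14 (3.90) lay below the level of 95% of olfactory receptor genes (4.17). The mean of the Dsg2 probes gave 0.49, and Krt14 and Dsc2 passed in 11 of the 13 alternative settings, not without shLDHA replicate 2 (adjusted p = 0.0595 and 0.0645). Camera gave an adjusted p of 3.13e-07 over the 6 groups, and the adjusted p was 0.0586 with an estimated correlation. Genes that ERK signalling induces and that feed back on it were lower on balance. Of 20, 11 fell and 0 rose, with a median of -0.45. Hbegf, a ligand of the EGF receptor, changed by -1.27, Phlda1 by -1.24, the phosphatase gene Dusp8 by -1.07, and the inhibitor genes Spred3 and Spry4 by -0.82 and -0.77. Of the same inhibitor families, Spry2 fell (-0.43), while Spry1 (0.14), Spred1 (-0.05) and Spred2 (-0.08) did not pass. Spry4 passed in 10 of the 13 settings, not without shLDHA replicate 1 (0.0735) or 2 (0.0872). The adjusted p of this group was 1.07e-12, and the adjusted p was 0.0586 with an estimated correlation. Of these genes, 6 are also in a fixed list, as are 3 of the desmosome group and 3 each of the centromere protein and kinesin groups below.

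Genes of DNA repair and the Fanconi pathway rose with the cell division genes. Of 16 tested, 9 rose and 0 fell, with a median of 0.54. Chek2 rose by 1.06, Neil3 by 0.90, Brca1 by 0.76 and Fancd2 by 0.66, which passed in 11 of the 13 settings, not without shLDHA replicate 1 (0.0601). Camera gave an adjusted p of 1.35e-10, and the adjusted p was 0.0586 with an estimated correlation. Of 20 centromere protein genes with symbols starting Cenp, 9 rose and 0 fell (median 0.43, adjusted p = 5.37e-09, and adjusted p = 0.133 with an estimated correlation). Of 25 histone genes, 8 rose and 0 fell (median 0.23, adjusted p = 1.65e-05, and adjusted p = 0.0602 with an estimated correlation), with a median of 0.42 over the members at or above the median level of all genes. Of 42 kinesin genes, 10 rose and 3 fell (median 0.11, adjusted p = 0.00186, and adjusted p = 0.163 with an estimated correlation). That median was 0.05 without scramble replicate 1, 0.21 without scramble replicate 2, 0.22 without shLDHA replicate 1 and 0.36 over the members at or above the median level of all genes. All 6 groups kept their direction in the 13 alternative settings.

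Genes that lie next to each other tended to change together, most of all on the chromosome that carries Nfkbiz, Ifnar2 and Il1rap. Of its 340 genes at or above the median level, 278 had a log2 change below 0, and 66 were lower past the threshold against 3 higher, with a median log2 change of -0.22. Over all 11027 such genes, 48.3% were below 0. On the chromosome of Myc and Ccn4 the median was 0.13 over 454 genes, with 57 higher and 16 lower past the threshold. In permuted gene orders the limits for the lowest and highest of 20 chromosome medians were -0.03 and 0.05. On the first of these chromosomes Nfkbiz changed by -1.29, the interferon receptor gene Ifnar2 by -0.79 (SE 0.10) and the interleukin 1 receptor subunit gene Il1rap by -0.72 (SE 0.09), all past the threshold, while the mean of the Il1rap probes gave -0.18, and Il1rap did not pass without shLDHA replicate 2 (0.0594). Medians beyond the permuted limits were not confined to the chromosomes named above. The chromosome of Cxcl1 had a median of 0.09, and that of Il1a and Lcn2 a median of -0.034 against a lower limit of -0.029. Another, with 626 such genes, had a median of 0.10, with 81 higher and 14 lower past the threshold. Subtracting the median change of 50 neighbouring genes left the 53 genes of both cell cycle lists at a median of 0.42, from 0.41.

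For these runs of neighbouring genes, array noise that neighbours share is argued against as the whole cause. The SD of medians over 51 genes in a row was 2.13 times its permuted value between groups and at most 1.29 times between replicates (p = 0.001 for each of the 3 contrasts, the smallest 1000 permutations can give). A difference in copy number between the cell pools may account for the runs, because the changes of genes 50 to 100 places apart still correlated at r = 0.0424 across genes (permuted upper limit 0.00258). Regulation shared over such long stretches was not tested, and DNA copy number was not analysed here. Whether such a difference would come from the knockdown, from puromycin or from chance in founding the pools stays open.

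The fall of cytokine and NF-kB target genes was weighed against other cells in the scramble cultures and against copy number. Leukocytes in the scramble cultures are argued against, since in scramble only Cd68, Cd14 and Fcer1g, 3 of 14 markers, lay above the level of 95% of olfactory receptor genes (4.17), while Ptprc (2.72) and Lyz2 (2.59) did not; Cd68 did fall, from 7.46 to 6.55, and a share of leukocytes too small to lift the other markers stays open. Fibroblasts in the scramble cultures are argued against too, since 1 of 10 markers, Pdgfra, lay above that level, at 6.52 in scramble and 6.49 in shLDHA, while Col1a1 (3.55) and Dcn (2.11) did not. The median change of 50 neighbouring genes was subtracted for 22 of the 23 called genes, those at or above the median level with a position. It left them at a median of -1.14, from -1.25. No median over 51 genes in a row exceeded 0.33 in size, so the subtraction could not have removed a fall this large. The values thus argue only against long shifted stretches around these genes as the whole cause. Copy number of shorter stretches, or of regulators that lie elsewhere, was not tested. A response to the loss of Ldha, a difference in puromycin selection, an effect of the hairpin on other transcripts, and a difference between the founding cells remain open, since the 4 arrays include no rescue of Ldha and no hairpin named as a separate one.

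Whether the Ldha probes also bind other transcripts, whether their signal compressed the fall of Ldha, and whether the knockdown was partial was not tested.

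Olfactory receptor genes, which are not known to act in mammary cells, gave 4 higher and 5 lower calls among 1105 tested, or 0.814%, against 6.36% of all genes. They were dim, with 95% of them below 4.17 in scramble, while the median brighter-group level of all genes was 4.10. Only 82 of the 1410 called genes lay below that median. The low share can therefore not be told apart from that of dim genes in general, and it does not test the calls of brighter genes.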
